A study of Oryctolagus cuniculus with 39 samples.

How the data were processed

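RNA of rabbit embryonic stem (ES) cell cultures and of pooled embryonic tissue was hybridised to 39 single-colour Agilent rabbit arrays, 1 array per culture or pool, placed on 7 slides and scanned on 2 days. Per the labels' protocols, total RNA was labelled with Cy3. The deposited scanner files hold, per the file headers, intensity values that Agilent Feature Extraction subtracted for local background and detrended within each array, with no normalization between arrays. The program version was 10.7.3.1 per the file headers and 9.1 per the submitters' processing notes. The same files hold spot and background intensity before any correction and the program's marks of 0 or 1 for spots that lay well above background, were saturated or were uneven, per the file headers. The series table deposited by the authors holds log2 values. Set against the scanner files, those values lay close to the log2 of the median spot intensity minus the array's own median, which places them on a log2 scale. The offset differed from the array median by 0.0306 to 0.0729 on the log2 scale, and the differences had an SD over probes of at most 0.0615. That table served as an alternative.

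Each array held 62976 spots, of which 61657 were not controls, for 42089 different probes. The working value was the log2 of the background-subtracted intensity of a spot, averaged over the spots of a probe that carried no mark for unevenness, minus the array's 75th percentile. A probe was kept when at least 3 arrays of 1 group had it well above background, which left 31898 probes. A further 88 of these were left out because all their spots were marked in some line or pool. No signal was 0 or negative, and 8 single values were saturated.

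Genes were named from the gene IDs and RefSeq accessions that the array files give with each probe, looked up in a gene table of assembly mOryCun1.1, which was used for names only. This named 20382 probes, and the symbol in the array file named 320 more. In all 19799 probes named exactly 1 gene with a symbol, 903 named a gene known only by a locus number, 53 named several genes and 21334 named none. Probe positions are those of the array files, on oryCun2. For each gene the kept probe with the highest mean signal was tested, which gave 7678 genes. POU5F1, SOX2, NANOG, KLF4, TFCP2L1, CDH2, SPRY4, SOCS3, GATA6 and CDX2, which were to be given wherever measured, had no named probe, and the probe for FGF5 did not pass the filter.

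The replicate was the cell line or the embryo pool. Signals of the cultures of a line were averaged, which gave 11 lines and 8 pools, 19 units in 7 groups. Groups were compared with limma 3.58.1 in R 4.3.3 (package data.table, version 1.17.8), by linear models with a mean for each group, a spread shared by all 7 groups, and moderated two-sided tests. Adjusted p-values are Benjamini-Hochberg values over the 7678 genes, and a gene passed at an adjusted p under 0.05. In the comparisons of ES lines with embryo tissue, the 5 culture types had equal weight in the ES mean. The type comparisons share lines and the ES comparisons share all 11 lines, so they are not independent of each other. A fold is a lower bound, written "at least", where the gene's tested probe lay well above background on no array of 1 side. The bound is taken against the array's lowest signal among probes well above background, or against the probe's own signal where that was higher. In the latter case the bound can equal the fold itself, so it is a limit by this rule only. Where the tested probe lay well above background on some but not most arrays of a side, no fold is given. A log2 fold change given for such a gene rests in part on signals near background.

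Gene lists for pluripotency states, signalling pathways, early lineages, other cell types and metabolism were written down before the data were examined, as were the comparisons, the tests, the other settings tried and the rule for the genes named. Of 25 lists, 21 had 5 or more tested members and were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the lists of a comparison. The same test with a correlation estimated per list, and fry, were alternatives. A second adjustment of gene p-values over the list alone is given beside the count over all genes. The genes named are, per comparison, the 8 with the largest positive and the 8 with the largest negative log2 fold change among those that passed with no overlap between the groups' units, up to 4 members of each list with the smallest adjusted p, and the fixed genes. Genes known only by a locus identifier were passed over. From these the text gives a selection, and some named genes are not reported here.

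The position of each line between ICM and epiblast was its projection on the line from the mean ICM profile (0) to the mean epiblast profile (1), over the genes that differed between both tissues. Embryo pools were placed on an axis made without them. A second measure was the correlation across genes with the mean epiblast profile minus that with the mean ICM profile. Lines with and without FGF2 were compared by exact two-sided permutation tests, adjusted over these 2 relations. These shuffle lines and not conditions, though FGF2 was set by condition, so their p-values do not allow for differences between conditions.

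The other settings were quantile normalization, normexp background correction (offset 50) with quantile normalization, the authors' series table, centring on the array median, a floor for low signals, other filters and probe rules, every culture as a replicate with and without a term for the line, slide as a block, each scan day alone, culture letter or pool number as a block, only the groups compared, limma's trend and robust settings, and leaving out each line or pool. In the fits by slide and by scan day every culture was its own replicate with the line as a random block, so their counts rest on more values than the counts by line. On the first scan day CKF had 1 array, and AKSF had 2 arrays, both of line 19. Results of that day rest on 1 array for CKF and on 1 line for AKSF. In simulated data with real means and spreads, the steps were tested before use on 7678 genes with 100 genes changed per fold size. For epiblast against ICM, 73% of 2-fold and 88% of 4-fold changes were recovered. The recovered share was 39% and 80% for AKF against CKF, 34% and 72% for AKSF against AKF, 41% and 78% for AKSF against AKSgff, 36% and 85% for AKSL against AKSgff, 56% and 80% for AKSL against AKSF, 65% and 92% for ES lines against ICM, and 73% and 96% for ES lines against epiblast.

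The share of spots well above background ran from 53.3% to 72.5% over the 39 arrays, and the number of lines and pools limits the precision. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 served for gene names and figures. Probes with no gene name, or with several, were left out of the main tests. Day 6 is the age the labels give for the epiblast, and epiblast pool 1 also carries a time of 120 h.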

Results

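Gene expression was measured in rabbit embryonic stem (ES) cell lines grown under 5 culture conditions and in the pluripotent tissues of the rabbit embryo, on 39 single-colour arrays. The embryo samples were 4 pools of inner cell mass (ICM), the cells of the day 4 blastocyst that go on to form the embryo, with 30 embryos in a pool, and 4 pools of epiblast, the pluripotent layer found at day 6, with 10 embryos in a pool. AKF (2 lines, 6 arrays) and CKF (2 lines, 4 arrays) grew in 20% knockout serum replacement (KOSR, a defined stand-in for serum) with the growth factor FGF2. AKF was passaged with accutase, an enzyme mix that gives single cells, and CKF with collagenase, which leaves clumps. AKSF (2 lines, 6 arrays), AKSgff (2 lines, 6 arrays) and AKSL (3 lines, 9 arrays) were passaged with accutase and grew in 10% KOSR and 10% fetal calf serum. AKSF had FGF2, AKSgff no growth factor, and AKSL the cytokine LIF. Line numbers 4, 8 and 20 occur in more than 1 condition, and these were treated as separate lines, 11 in all. Each condition had its own lines, so a difference between conditions is also a difference between lines.

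The mean share of spots well above background was 60.8% in epiblast, 62.2% in ICM, 67.0% in AKF, 60.6% in AKSF, 66.7% in AKSL, 65.5% in AKSgff and 70.0% in CKF. Signals are normalized log2 intensities with the array's 75th percentile at 0, so negative values lie below it. Over 7678 genes, cultures of the same line correlated at a median r of 0.978 (29 pairs of arrays), lines of the same condition at 0.972, lines of different conditions at 0.953, and lines with embryo pools at 0.878. These correlations run across genes, which are not independent replicates. Scaling moved the median log2 fold change of all genes. For epiblast against ICM it was 0.01, and −0.15 with the authors' series table and −0.20 with centring on the array median. For ES lines against epiblast it was −0.10, 0.15 and 0.18, and −0.14 with a floor for low signals. A floor moved it from −0.07 to −0.11 for ES lines against ICM, and centring on the array median from 0.03 to 0.11 for AKSL against AKSgff. Changes below are relative to the array's 75th percentile. Before scaling, that percentile lay at 8.45 to 9.25 in ICM and 8.91 to 9.48 in epiblast. In the lines it ran from 9.83 (AKSL) to 10.80 (CKF), with no overlap. Signal near background can therefore sit higher in the pools than in the lines, which bears on dim genes when lines are compared with tissue. The first principal component (47.9% of the variance) ran from ICM (−89.0 to −82.3) through epiblast (−28.8 to −24.3) to the ES lines (24.3 to 49.9). The second (16.3%) also parted epiblast from ICM. On the third (12.4%), CKF lines 4 and 8 lay at −72.0 and −60.4, and the other 9 lines between −14.8 and 31.8.

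Epiblast against ICM asked how the pluripotent cells of the embryo change between day 4 and day 6. Genes of naive pluripotency, the ground state of the early embryo, were lower in the epiblast. Of 11 measured members, 7 fell and 4 did not pass, and the list lost its call with an estimated correlation between genes (adjusted p = 0.136 with an estimated correlation). The nuclear receptor ESRRB was at least 15.3-fold lower (log2 fold change −4.19 ± 0.27 SE, adjusted p = 1.78e-08), the transcription factor KLF5 20.6-fold lower (−4.37 ± 0.27, adjusted p = 1.31e-08) and NODAL, a signal of the TGF-beta family, 4.47-fold lower. Of 8 measured genes of the LIF and STAT3 response, 6 fell, among them IL6ST, the signalling receptor that LIF shares with other cytokines (11.5-fold lower, −3.52 ± 0.27, adjusted p = 9.95e-08). The naive list and the LIF and STAT3 list share members, among them KLF5, GBX2 and IL6ST, so they are not separate results. All 9 measured genes of oxidative phosphorylation fell, by less, among them the complex I subunit NDUFS1 (−0.77 ± 0.12, adjusted p = 6.46e-05) and the cytochrome c oxidase subunit COX5B (−0.83, adjusted p = 7.45e-05).

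Among single genes, the largest rise was that of CALB1, a calcium-binding protein, from −6.80 ± 0.49 (SD, n = 4) in ICM to 1.60 ± 0.09 (n = 4) in epiblast, at least 195-fold (adjusted p = 4.59e-12, probe at chromosome 3, 105511349 to 105511408, oryCun2). RRAGD, a GTPase that relays amino acid supply to mTORC1, rose 79.7-fold (adjusted p = 1.41e-10) and the carbonic anhydrase CA4 63.2-fold (adjusted p = 4.95e-06), and the iron carrier transferrin (TF) rose as well (log2 fold change 6.26, adjusted p = 4.48e-05). SFRP2, a secreted modulator of Wnt signals, rose 18.5-fold (adjusted p = 2.57e-07), as did LEF1, a transcription factor of the Wnt pathway (2.64, adjusted p = 0.00086). Lower in the epiblast were MAGEB17 (at least 45.0-fold, adjusted p = 4.06e-07), the homeobox gene GSC (53.1-fold, adjusted p = 1.36e-06) and the trophoblast regulator GCM1 (at least 12.7-fold, adjusted p = 6.57e-07). E-cadherin (CDH1), the adhesion molecule of epithelial and pluripotent cells, was 1.91-fold lower (−0.93 ± 0.24, adjusted p = 0.00435), and OTX2, a transcription factor of the primed state, was 2.51-fold higher (1.33 ± 0.51, adjusted p = 0.0399). The de novo methyltransferase DNMT3B (0.54, adjusted p = 0.0706), the ERK phosphatase DUSP6 (0.25, adjusted p = 0.389) and COL1A1 (0.56, adjusted p = 0.453) did not pass.

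In all, 4081 of 7678 genes passed in limma, 2092 higher and 1989 lower in the epiblast, 2065 of them by more than 2-fold. Scaling decided the balance of directions. It was 1602 higher and 2524 lower with the authors' series table, and 1638 and 2684 with centring on the array median. The 7 naive, 6 LIF and STAT3 and 9 oxidative phosphorylation genes also fell when adjusted over the list alone. The lists moved as sets in camera, with adjusted p = 0.00229, 0.0144 and 0.00229 and median log2 fold changes of −2.16, −1.15 (−0.95 with dim genes at their bound) and −0.67. The calls of the other 2 lists were also lost with an estimated correlation (adjusted p = 0.427 and 0.410 with an estimated correlation), and that of the LIF and STAT3 list also with a strict filter on dim probes (0.0879). Of 11 primed pluripotency genes 5 rose, but the list did not pass (adjusted p = 0.0517). As a block, slide left 3418 genes past the test, and 2806 and 1996 within the first and second scan day. The calls of CDH1 (adjusted p = 0.0791 with slide as a block, 0.558 on the second day) and OTX2 (0.161 with slide as a block, 0.467 and 0.254 within the days) ended there. That of OTX2 also ended without epiblast pool 1, 2, 3 or 4 (adjusted p = 0.0688, 0.0702, 0.0752 and 0.0610) and without ICM pool 1, 2 or 4 (0.108, 0.0660 and 0.0510).

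**Figure D1:**
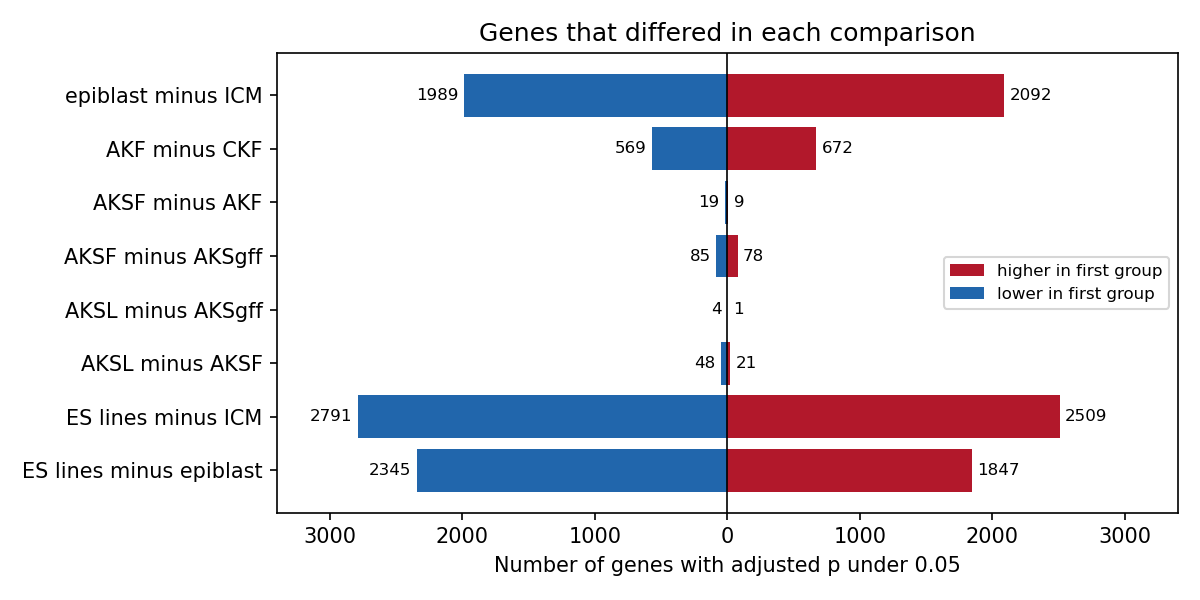
Number of genes with an adjusted p under 0.05 in each of the 8 comparisons, as bars to the right for genes higher and to the left for genes lower in the first-named group. Counts run from 5 genes (AKSL against AKSgff) to 5300 (ES lines against ICM).

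AKF against CKF set passaging as single cells against passaging in clumps, with the same medium. Epithelial genes were higher in the AKF lines. Of 10 measured members 8 rose and 2 did not pass, and the list lost its call with an estimated correlation (adjusted p = 0.273 with an estimated correlation). CDH1 rose at least 11.4-fold, from −8.03 ± 0.64 (SD, n = 2) in CKF to −3.81 ± 0.60 (n = 2) in AKF (log2 fold change 4.22 ± 0.34 SE, adjusted p = 4.55e-06, probe at chromosome 5, 24299471 to 24299530, oryCun2). The tight junction gene CLDN7 rose 13.6-fold (adjusted p = 0.000187) and the epithelial adhesion molecule EPCAM 8.57-fold (adjusted p = 0.000427). DNMT3B was 8.65-fold higher (3.11 ± 0.34, adjusted p = 6.06e-05). Of 11 naive pluripotency genes 4 rose, led by PECAM1, an adhesion molecule of endothelial and ES cells (4.93 ± 0.33, adjusted p = 2.46e-06), and NODAL (4.83-fold, adjusted p = 7.34e-05). Of 17 genes of the response to FGF and ERK 5 rose, among them the phosphatase DUSP5 (4.06-fold, adjusted p = 0.000279) and DUSP6 (2.05-fold, adjusted p = 0.045). Of 11 targets of serum and YAP, the mechanical signal route, 2 rose, CCN1 (3.38-fold, adjusted p = 0.0166) and MYL9 (0.89 on the log2 scale, adjusted p = 0.0387).

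Among the largest rises were those of the lens membrane protein LIM2 (log2 fold change 6.22, adjusted p = 0.000458) and NDUFAF2, an assembly factor of complex I (45.9-fold, 5.52 ± 0.39, adjusted p = 2.46e-06). Alpha-fetoprotein (AFP), a product of yolk sac and fetal liver, was at least 24.1-fold higher (adjusted p = 0.000421). Among the genes higher in CKF were RSPO3, a secreted enhancer of Wnt signals (50.3-fold, adjusted p = 0.000243), the homeobox gene HOXA11 (49.6-fold, −5.63 ± 0.62, adjusted p = 6.06e-05), the eye and neural transcription factor PAX6 (41.6-fold, −5.38 ± 0.48, adjusted p = 1.18e-05) and the neural tube gene DBX1 (−4.67, adjusted p = 0.00204). OTX2 (0.88, adjusted p = 0.456), ESRRB (0.18, adjusted p = 0.81) and COL1A1 (1.55, adjusted p = 0.242) did not pass.

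In limma 1241 genes passed, 672 higher and 569 lower in AKF, 831 of them by more than 2-fold. Adjusted over the list alone, 9 epithelial, 4 naive (with 1 more lower), 7 FGF and ERK and 3 serum and YAP genes rose. In camera the epithelial list rose with a median of 2.74 (2.62 with dim genes at their bound, adjusted p = 4.01e-08), but not with an estimated correlation (adjusted p = 0.273 with an estimated correlation). The naive list (median 0.80, adjusted p = 0.0233, 0.277 with an estimated correlation), the FGF and ERK list (0.78, adjusted p = 0.0103, 0.350 with an estimated correlation) and the serum and YAP list (1.03, adjusted p = 0.0231, 0.489 with an estimated correlation) rose likewise. There were 2258 genes with slide as a block and 1422 within the second scan day. The first day had 1 CKF array, so no count or p-value is given for it. The epithelial list kept its call with slide as a block and on the second day (medians 2.91 and 2.25, and 3.95 on the first day). With slide as a block the naive (adjusted p = 0.0526), FGF and ERK (0.0741) and serum and YAP (0.0526) lists lost their calls. The naive list also lost its call on the second day (0.0778) and with normexp (0.0738). The calls of DUSP5, DUSP6, CCN1 and MYL9, and of the FGF and ERK and the serum and YAP lists, were not kept on the first day. The count was 438 without AKF line 20, 757 without AKF line 5, 719 without CKF line 4 and 722 without CKF line 8. Without AKF line 5 the adjusted p of the naive, FGF and ERK and serum and YAP lists was 0.0646, 0.0673 and 0.0719, and that of the last was 0.184 without CKF line 8. DUSP6 and MYL9 lost their calls without any 1 of these 4 lines (adjusted p from 0.0935 to 0.246 and from 0.120 to 0.172), and CCN1 without AKF line 5 (0.0959), AKF line 20 (0.0685) or CKF line 8 (0.125).

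AKSF against AKF set medium with fetal calf serum against serum replacement alone, with FGF2 and accutase in both. Few genes differed. SOCS2, a feedback inhibitor of cytokine signalling, was 5.65-fold higher with serum, at 2.55 ± 0.33 (SD, n = 2) against 0.05 ± 0.05 (n = 2) in AKF (adjusted p = 0.0041). ANXA8, an annexin, was 8.10-fold higher (3.02 ± 0.39 SE, adjusted p = 0.00394), HOXA11 10.5-fold (3.40 ± 0.62, adjusted p = 0.035) and BAMBI, a decoy receptor of BMP signals, 2.71-fold (1.44 ± 0.25, adjusted p = 0.0229). SPARCL1, a secreted matrix protein, was lower (−5.50 ± 0.78, adjusted p = 0.00516, probe at chromosome 15, 62699301 to 62699947, oryCun2) and PAX6 8.36-fold lower (−3.06 ± 0.48, adjusted p = 0.0111).

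In limma 28 genes passed, 9 higher and 19 lower in AKSF, and the split was 13 and 17 with low signals set to a floor. With only the groups compared in the limma fit 0 passed (1118 at an unadjusted p under 0.05). Of 7 BMP response genes BAMBI alone rose, and 3 rose and 1 fell adjusted over the list alone (median 0.70, camera adjusted p = 0.00647, 0.0876 with an estimated correlation). No gene of cholesterol synthesis passed over all genes, and 3 of 11 fell adjusted over the list alone. FDFT1, which makes squalene, stood at −0.87 (adjusted p = 0.154 over all genes). As a list they fell in camera (median −0.54, adjusted p = 0.000344, but adjusted p = 0.640 with an estimated correlation). The FGF and ERK list (17 genes, 2 lower adjusted over the list alone, median −0.46, adjusted p = 0.0291) fell and the cell cycle list (17 genes, median 0.12, adjusted p = 0.0476) rose as sets with no member past the test over all genes, and neither with an estimated correlation (adjusted p = 0.640 with an estimated correlation for each list). Neither call was kept with slide as a block (adjusted p = 0.113 for each list) or on the first scan day (0.0964 and 0.427), nor that of the FGF and ERK list on the second (0.0760) or with a strict filter (0.130), nor that of the cell cycle list with the authors' series table (0.101), normexp (0.0561), a floor (0.127), no filter (0.282) or a strict filter (0.0509). The fixed genes CDH1 (−0.10, adjusted p = 0.992), DUSP6 (−0.46, 0.824), DNMT3B (−0.19, 0.962), OTX2 (−0.71, 0.913) and COL1A1 (−1.10, 0.856) did not pass. Slide as a block gave 240 genes, and the scan days 659 (345 higher and 314 lower) and 146, with 25, 25 and 23 of the 28 among them. The AKSF arrays of the first day were all of line 19. The comparison depended on single lines, most on AKF line 5. Without it 0 genes passed in limma (379 at an unadjusted p under 0.05), against 45 without AKF line 20, 11 without AKSF line 19 and 4 without AKSF line 26, and the FGF and ERK list had an adjusted p of 0.282. Without AKSF line 26 the adjusted p was 0.112 for SPARCL1, 0.276 for HOXA11, 0.276 for BAMBI and 0.0991 for PAX6, and without AKSF line 19 it was 0.0532 for SOCS2, 0.110 for HOXA11 and 0.110 for PAX6. The cell cycle list had an adjusted p of 0.347 without AKF line 20 and 0.318 without AKSF line 26, and the FGF and ERK list 0.499 without AKSF line 19.

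AKSF against AKSgff set FGF2 against no growth factor in serum medium, in separate lines, so FGF2 and line cannot be told apart. Genes that FGF signals switch on through ERK were higher with FGF2. Of 17 measured members 5 rose and 12 did not pass. DUSP6, the ERK phosphatase that the pathway induces against itself, rose 4.67-fold (2.22 ± 0.33 SE, adjusted p = 0.00247), the ETS factor ETV5 3.67-fold (1.87 ± 0.29, adjusted p = 0.00337) and DUSP5 3.54-fold (adjusted p = 0.00252). Brachyury (TBXT), the transcription factor that marks the primitive streak and early mesoderm, rose at least 74.6-fold, from −7.78 ± 0.11 (SD, n = 2) in AKSgff to −0.50 ± 0.64 (n = 2) in AKSF (adjusted p = 0.00282, probe at chromosome 12, 155293962 to 155294021, oryCun2). RSPO3 (log2 fold change 5.38 ± 0.74, adjusted p = 0.0012), HOXA11 (5.29 ± 0.62, adjusted p = 0.000531) and HOXB1, a hindbrain homeobox gene (3.92 ± 0.43, adjusted p = 0.000354), rose from levels well above background on few AKSgff arrays.

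Lower with FGF2 were the cytokine IL20 (log2 fold change −8.45 ± 0.64, adjusted p = 6.5e-06) and the transglutaminase TGM3 (at least 55.6-fold, adjusted p = 0.001). DPPA5, an RNA-binding protein of naive pluripotent and germ cells, lay at −7.08 ± 0.18 (SD, n = 2) with FGF2 and −1.25 ± 0.15 (n = 2) without, at least 29.5-fold lower (adjusted p = 6.05e-05, probe at chromosome 12, 60172378 to 60172785, oryCun2). It was 1 of 2 naive genes of 11 that fell, the other being TBX3 (3.82-fold, adjusted p = 0.0343). Of 11 trophectoderm genes 2 fell, FGFR2, a receptor for FGFs (−1.90 ± 0.30, adjusted p = 0.00355), and the epithelial factor ELF3 (2.95-fold, adjusted p = 0.0466). Of 11 primed genes 3 rose (DUSP6, ETV5 and SFRP2), of 9 Wnt response genes 2 (TBXT and the Wnt inhibitor DKK1), and of 8 primitive streak and mesoderm genes 2 rose (TBXT and EVX1) and 1, GSC, fell (log2 fold change −3.46 ± 0.81, adjusted p = 0.0407). Of 13 fibroblast genes COL5A1 alone rose (2.80-fold, adjusted p = 0.0212). CDH1 (−0.96, adjusted p = 0.206), ESRRB (−0.99, 0.245), OTX2 (−1.21, 0.553), DNMT3B (0.17, 0.916) and COL1A1 (−0.45, 0.908) did not pass.

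In limma 163 genes passed, 78 higher and 85 lower with FGF2 (306 and 524 over all kept probes, 25 and 44 without AKSgff line 62). In camera the FGF and ERK list rose (median 1.07, 0.96 with dim genes at their bound, adjusted p = 3.4e-09) and kept its call with an estimated correlation (adjusted p = 0.0246 with an estimated correlation). It also kept its call in both scan days, on the first with AKSF line 19 alone. Adjusted over the list alone, 8 of its members rose. No other list kept its call with an estimated correlation. These were the primed list (median 0.63, adjusted p = 0.00783, 0.0751 with an estimated correlation, 3 members higher adjusted over the list alone), Wnt response (0.35, 0.00783, 0.0943 with an estimated correlation, 2 higher), primitive streak and mesoderm (0.60, 0.0331, 0.156 with an estimated correlation, 2 higher and 1 lower), fibroblast (0.38, 0.00400, 0.156 with an estimated correlation, 3 higher), mesenchymal (7 genes, 0.38, 0.0331, 0.156 with an estimated correlation, 1 higher) and serum and YAP targets (11 genes, 0.48, 0.0389, 0.400 with an estimated correlation, no member higher). The naive list (median −0.41, adjusted p = 0.00783, 0.0978 with an estimated correlation, 4 members lower and 1 higher adjusted over the list alone), the trophectoderm list (−1.27, 0.00228, 0.102 with an estimated correlation, 4 lower) and the immune and interferon list (7 genes, −0.58, 0.0272, 0.327 with an estimated correlation, 1 lower) fell as sets.

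Fits with slide as a block gave 822 genes, and those within the scan days 1099 and 389, with 156, 143 and 131 of the 163 among them. The AKSF arrays of the first day were all of line 19. On the first day the calls of 7 lists ended, with adjusted p = 0.0508 for naive, trophectoderm and Wnt response, 0.104 for fibroblast, 0.128 for mesenchymal, 0.303 for immune and interferon and 0.658 for primitive streak and mesoderm, and that of serum and YAP targets ended with slide as a block (0.102), on the second day (0.392) and with quantile normalization (0.0771), the authors' series table (0.0677), centring on the array median (0.0727), no filter (0.0773) and a strict filter (0.207). Centring on the array median also ended those of the mesenchymal (0.0507) and primitive streak and mesoderm (0.0579) lists, and no filter that of the mesenchymal list (0.0571). DUSP5 (0.0506), ELF3 (0.0758) and COL5A1 (0.122) did not pass on the second day. The count was 90 without AKSF line 19, 53 without AKSF line 26, 50 without AKSgff line 3 and 69 without AKSgff line 62. TBX3, ELF3 and COL5A1 lost their calls without any 1 of these 4 lines (adjusted p from 0.130 to 0.247, from 0.0585 to 0.415 and from 0.0512 to 0.265). Without AKSF line 26, EVX1 (0.211) and DKK1 (0.116) and the primitive streak and mesoderm (0.257), mesenchymal (0.0860) and immune and interferon (0.286) lists did not pass. Without AKSF line 19 this held for GSC (0.286), SFRP2 (0.0714) and the serum and YAP list (0.209). Without AKSgff line 3 it held for GSC (0.358), EVX1 (0.166), SFRP2 (0.0925) and the serum and YAP (0.195), mesenchymal (0.0703) and immune and interferon (0.107) lists, and without AKSgff line 62 for GSC (0.0756), EVX1 (0.0880), DKK1 (0.0645) and the primitive streak and mesoderm list (0.0915).

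AKSL against AKSgff set LIF against no growth factor in serum medium, again in separate lines, so LIF and line cannot be told apart. CCS, the copper chaperone of superoxide dismutase, was 7.40-fold higher with LIF, at 0.86 ± 0.38 (SD, n = 3) against −2.03 ± 0.64 (n = 2) (log2 fold change 2.89 ± 0.31 SE, adjusted p = 0.0012). MATCAP2, a tubulin peptidase, was at least 10.2-fold lower (−4.35 ± 0.54, adjusted p = 0.00371), IL20 lower (−3.46 ± 0.58, adjusted p = 0.0482), the fibrinogen chain FGG at least 3.37-fold lower (adjusted p = 0.0246) and BRDT, a chromatin reader of male germ cells, lower (−2.65 ± 0.39, adjusted p = 0.0201). Another probe of MATCAP2 lay well above background on 1 AKSL array. No member of the LIF and STAT3 list passed, and its 8 measured genes had a median of −0.09 (camera adjusted p = 0.569). Only 10 of the 21 genes of that list had a named probe, and SOCS1, SOCS3, KLF4 and TFCP2L1 had none. In simulated data 36% of 2-fold changes were recovered for this comparison, so a response to LIF is not excluded. ESRRB (−0.91, adjusted p = 0.657), DPPA5 (−2.37 ± 0.49, 0.138) and CDH1 (−0.43, 0.999) did not pass either.

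In limma 5 genes passed (413 at an unadjusted p under 0.05), 1 higher and 4 lower. With only the groups compared in the limma fit 0 passed (694 at an unadjusted p under 0.05). In camera the naive list (11 genes, 2 lower adjusted over the list alone, median −0.62, adjusted p = 0.00299) and the trophectoderm list (11 genes, 1 lower adjusted over the list alone, −0.80, adjusted p = 0.000971) fell and the fibroblast list (13 genes, none past adjusted over the list alone, 0.49, adjusted p = 0.000971) rose as sets. Each call was lost with an estimated correlation (adjusted p = 0.168 with an estimated correlation for each list), and on the first scan day that of the naive (0.148) and fibroblast (0.307) lists. With a block for slide 124 genes passed, and 305 and 3 within the scan days, with 5, 5 and 2 of the 5 among them. The count was 8 without AKSL line 20, and 3 without AKSgff line 3 or without AKSgff line 62. On the second day IL20 (0.164), FGG (0.0597) and BRDT (0.197) did not pass. IL20 lost its call without any 1 of the 5 lines (adjusted p from 0.0539 to 0.648), FGG without AKSL line 4 (0.111), AKSL line 8 (0.0806), AKSgff line 3 (0.298) or AKSgff line 62 (0.111), BRDT without AKSgff line 3 (0.398) and MATCAP2 without AKSgff line 62 (0.0686), as did the fibroblast list without AKSL line 20 (0.0631) or AKSgff line 3 (0.0761).

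AKSL against AKSF set LIF against FGF2 in serum medium, in separate lines. LIF, the lack of FGF2 and line cannot be told apart here. FGF and ERK genes were lower in the lines with LIF than in those with FGF2. Of 17 measured members 5 fell, among them DUSP6 (3.84-fold, −1.94 ± 0.30 SE, adjusted p = 0.00513), ETV5 (2.88-fold, adjusted p = 0.0107) and DUSP5 (2.94-fold, adjusted p = 0.00625). TBXT (adjusted p = 0.00486) and RSPO3 (adjusted p = 0.00111) were lower, each well above background on all 6 AKSF arrays and on 2 of 9 AKSL arrays, so no size is given. HOXA11 was 24.1-fold lower (−4.59 ± 0.57, adjusted p = 0.00111) and HOXB1 8.68-fold lower (adjusted p = 0.00111). Higher in AKSL than in AKSF were IL20 (5.00 ± 0.58, adjusted p = 0.000962) and DPPA5 (at least 5.70-fold, 3.47 ± 0.49, adjusted p = 0.0032), which lay at −3.62 ± 1.06 (SD, n = 3) with LIF. Against AKSgff, without a growth factor, IL20 was lower in AKSL (−3.46, limma adjusted p = 0.0482). DPPA5 did not pass there (−2.37, limma adjusted p = 0.138), so neither gene was raised over the lines with no factor. No member of the LIF and STAT3 list passed (8 genes, median −0.20, camera adjusted p = 0.280), nor did CDH1 (0.52, adjusted p = 0.614) or OTX2 (1.77, adjusted p = 0.327). The measured part of that list again lacks SOCS1, SOCS3, KLF4 and TFCP2L1.

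In limma 69 genes passed, 21 higher and 48 lower with LIF. In camera the FGF and ERK list fell (10 members lower adjusted over the list alone, median −1.17, adjusted p = 1.2e-11), as did the primed list (11 genes, 2 lower over all genes, 5 lower and 2 higher adjusted over the list alone, −1.19, adjusted p = 0.00317), and both kept their calls with an estimated correlation (adjusted p = 0.00959 and 0.0331 with an estimated correlation). Both lists hold DUSP6, ETV4 and ETV5, so they are not separate results. The primitive streak and mesoderm list (8 genes, 2 lower, and 2 adjusted over the list alone, −0.75, adjusted p = 0.00277, 0.0654 with an estimated correlation) and the Wnt response list (9 genes, 2 lower, and 2 adjusted over the list alone, −0.23, adjusted p = 0.0098, 0.0780 with an estimated correlation) lost theirs, and also on the first scan day (0.155 for each). With no filter on dim probes the primed (0.0760) and Wnt response (0.0859) lists did not pass. Blocking for slide gave 413 genes (222 higher and 191 lower with LIF), and the scan days 777 (341 and 436) and 229 (114 and 115), so the balance of directions was not kept, with 65, 57 and 60 of the 69 among them. The AKSF arrays of the first day were all of line 19. The count was 45 without AKSF line 19, 15 without AKSF line 26 and 41 without AKSL line 4, with 8 higher and 7 lower without AKSF line 26. In the same run the calls of TBXT (0.0957), DUSP6 (0.125), ETV5 (0.125) and DUSP5 (0.148) and of the primitive streak and mesoderm list (0.0534) ended, as did that of ETV5 without AKSF line 19 (0.0806) and that of DUSP5 on the second scan day (0.0593).

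**Figure D2:**
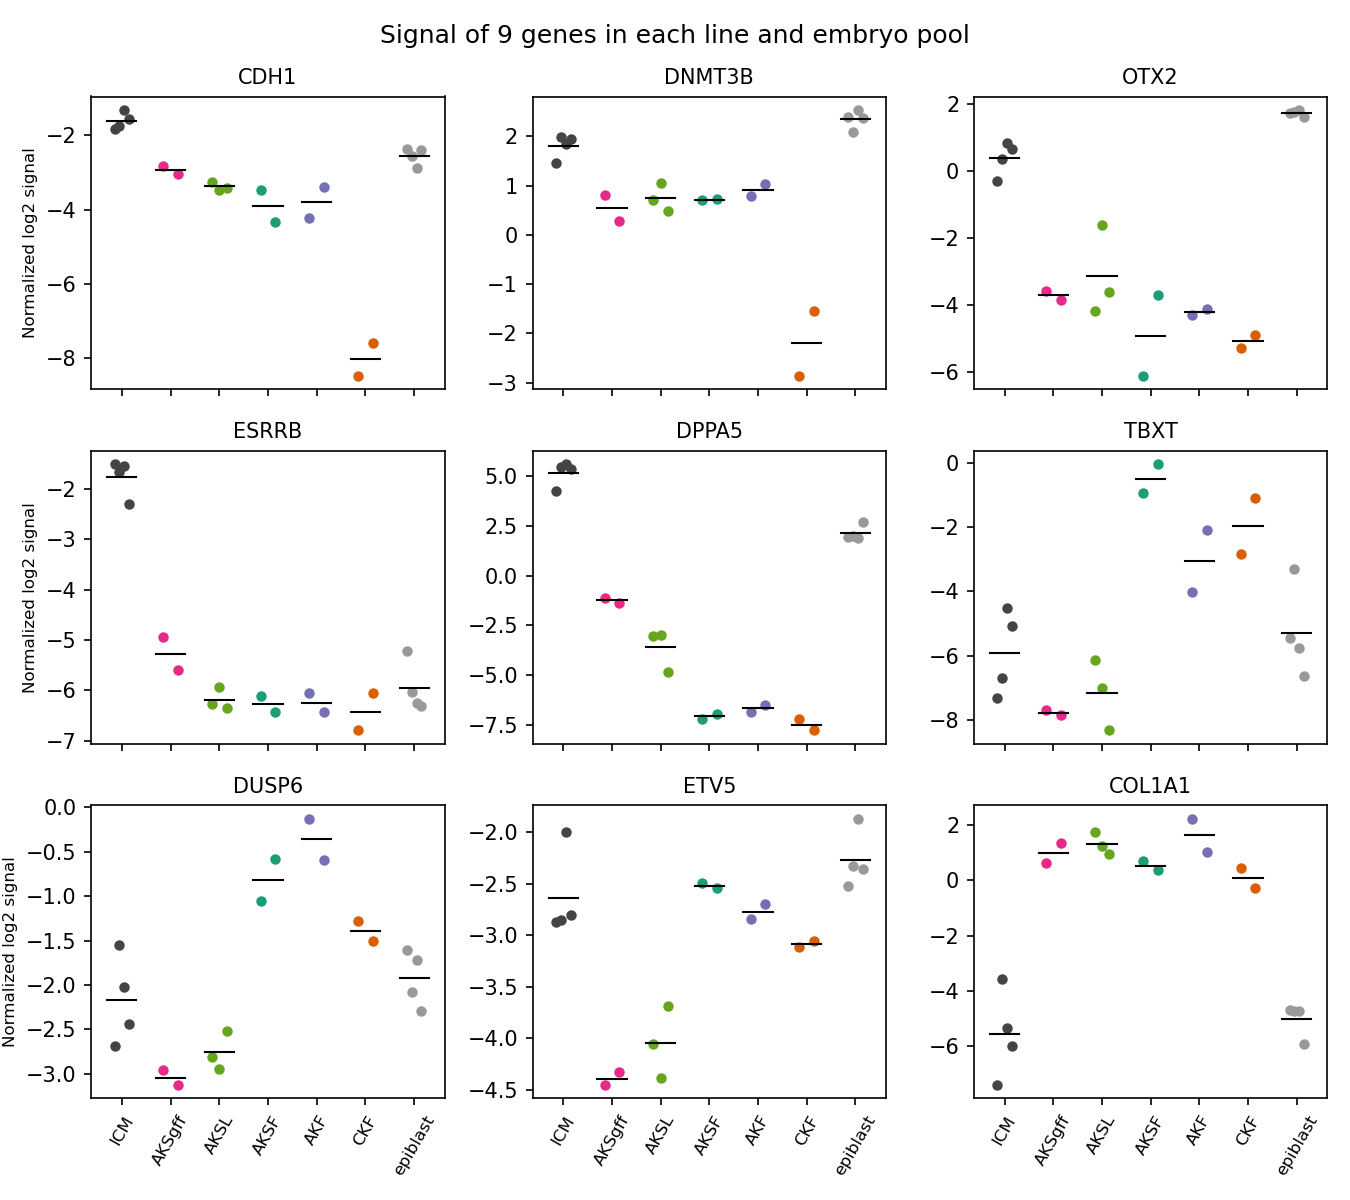
Normalized log2 signal (y axis) of 9 genes in each ES line and embryo pool (points), by group (x axis), with the mean of each group as a line. CDH1 lay at −8.03 in CKF and −3.81 in AKF, TBXT at −0.50 in AKSF and −7.78 in AKSgff, and DPPA5 at 5.19 in ICM and −7.08 in AKSF.

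ES lines against ICM asked how far the lines as a whole stood from day 4 pluripotent cells. Genes of fibroblasts and contractile matrix-producing cells were higher in the lines. Of 13 measured members 11 rose and DCN fell, and the list lost its call with an estimated correlation (adjusted p = 0.378 with an estimated correlation). The smooth muscle actin ACTA2 rose at least 254-fold (9.21 ± 0.35 SE, adjusted p = 2.98e-11, probe at chromosome 18, 36857883 to 36857942, oryCun2), the fibrillar collagen COL3A1 at least 229.8-fold (8.45 ± 0.35, adjusted p = 5.58e-11) and COL1A1 rose too (6.50 ± 0.50, adjusted p = 2.7e-08). Of 11 serum and YAP targets 8 rose, among them MYL9 (12.8-fold) and VCL, which links actin to adhesion sites (3.18-fold). Of 7 immune and interferon genes 5 rose, such as B2M, the light chain of MHC class I (4.34-fold, adjusted p = 5.65e-09). Of 11 genes of cholesterol synthesis 9 fell, among them the lanosterol synthase LSS (4.00-fold, adjusted p = 4.59e-09), and all 9 genes of oxidative phosphorylation fell, such as COX5B (2.14-fold, adjusted p = 2.91e-07).

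DPPA5 fell from 5.19 ± 0.61 (SD, n = 4) in ICM to a mean of −5.23 ± 2.52 (n = 11) in the lines (adjusted p = 3.26e-12). The conditions differed widely, from −1.25 in AKSgff to −7.52 in CKF. The gluconeogenic enzyme FBP1 (log2 fold change −7.14 ± 0.34, adjusted p = 1.99e-10), ESRRB (−4.31 ± 0.22, adjusted p = 4.47e-10) and CDH1 (−2.80, adjusted p = 1.2e-08) were lower. For these 4 genes no fold is given, since at least 1 condition had no array well above background. KLF5 was 34.9-fold lower (adjusted p = 7.98e-11), OTX2 24.2-fold lower (−4.60 ± 0.42, adjusted p = 1.89e-07) and DNMT3B 3.17-fold lower (adjusted p = 3.03e-06). For CDH1 and DNMT3B the CKF lines, which lay far below the AKF lines, pull the mean of the lines down. The intermediate filament gene NES, of neural progenitors, was at least 112-fold higher (7.79 ± 0.19, adjusted p = 3.69e-13), as was COL8A1, at least 238-fold (9.21 ± 0.22, adjusted p = 3.69e-13). DUSP6 was 1.41-fold higher (adjusted p = 0.0319).

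In limma 5300 genes passed, 2509 higher and 2791 lower in the lines, 2773 of them by more than 2-fold. In camera the fibroblast (median 2.28, adjusted p = 0.000488), serum and YAP (1.67, adjusted p = 0.00677) and immune and interferon (2.12, adjusted p = 0.0332) lists rose and the cholesterol (−1.42, adjusted p = 0.00274) and oxidative phosphorylation (−0.66, adjusted p = 0.00677) lists fell. Their members past the test adjusted over the list alone numbered 12, 8, 5, 9 and 9. No list kept its call with an estimated correlation (adjusted p = 0.378 for fibroblast and 0.512 for the other lists with an estimated correlation). With the authors' series table the immune and interferon (adjusted p = 0.344), oxidative phosphorylation (0.480) and serum and YAP (0.0503) lists did not pass. A floor (0.0512) and leaving out ICM pool 4 (0.0548) ended the call of the immune and interferon list, quantile normalization (0.0557) and the first scan day (0.1003) that of oxidative phosphorylation, and a strict filter those of the cholesterol (0.0549) and serum and YAP (0.0812) lists. There were 4991 genes with slide as a block, and 4505 and 3857 within the scan days. DUSP6 lost its call with slide as a block (adjusted p = 0.148), within either day (0.263 and 0.185), and without ICM pool 1 (0.152), ICM pool 4 (0.108), AKF line 5 (0.0580), AKSF line 26 (0.0580), AKSgff line 3 (0.0512) or CKF line 4 (0.0515).

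ES lines against epiblast asked the same of day 6 cells. Of the 13 fibroblast genes 11 rose here as well and DCN fell, and the list's call was lost with an estimated correlation (adjusted p = 0.195 with an estimated correlation). COL3A1 rose at least 189-fold (8.00 ± 0.35 SE, adjusted p = 4.61e-10), ACTA2 at least 208-fold (8.14 ± 0.35, adjusted p = 4.61e-10) and COL1A1 rose too (5.94 ± 0.50, adjusted p = 2.64e-07). Of 11 serum and YAP targets 10 rose, of 7 immune and interferon genes 6, among them B2M (4.12-fold, adjusted p = 3.61e-08), and of 10 glycolysis genes 7, among them GPI (2.97-fold, 1.57 ± 0.11, adjusted p = 5.23e-08) and ALDOC (7.56-fold, adjusted p = 1.58e-07), while PFKM fell. Of 11 cholesterol synthesis genes 8 fell, such as LSS (2.45-fold, adjusted p = 1.42e-06).

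OTX2 was 60.7-fold lower in the lines (−5.92 ± 0.42, adjusted p = 5.5e-08), HESX1, a homeobox gene of the anterior neural plate, 113-fold (−6.82 ± 0.26, adjusted p = 1.01e-10) and DNMT3B 4.61-fold (−2.20 ± 0.20, adjusted p = 5.17e-07). Also lower, with no fold given for the same reason, were CALB1 (−7.04 ± 0.18, adjusted p = 1.96e-12), DPPA5 (−7.36 ± 0.32, adjusted p = 4.34e-10), CDH1 (−1.86, adjusted p = 2.5e-06), the pancreatic enzyme gene CPB1 (−9.11 ± 0.55, adjusted p = 1.18e-08) and APOA1, the main protein of HDL (−6.30 ± 0.81, adjusted p = 1.56e-05). The CKF lines, far below the AKF lines in CDH1 and DNMT3B, pull the means of these genes down. In the other conditions CDH1 ran from −3.90 (AKSF) to −2.94 (AKSgff). ESRRB (−0.13, adjusted p = 0.648) and DUSP6 (0.25, adjusted p = 0.284) did not pass. Of 11 primed genes 4 rose and 4 fell (camera adjusted p = 0.982).

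In limma 4192 genes passed, 1847 higher and 2345 lower in the lines. Here too the balance turned with the scaling, to 2258 higher and 1882 lower with normexp, 3179 and 1746 with the authors' series table and 2803 and 1499 with centring on the array median. In camera the fibroblast (median 2.48, 1.93 with dim genes at their bound, adjusted p = 2.15e-05, 0.195 with an estimated correlation), serum and YAP (1.73, 2.15e-05, 0.195 with an estimated correlation), glycolysis (0.51, 0.00821, 0.359 with an estimated correlation) and immune and interferon (1.34, 0.69 with dim genes at their bound, 0.00821, 0.359 with an estimated correlation) lists rose and the cholesterol list (−0.80, 0.00821, 0.754 with an estimated correlation) fell. Their members past the test adjusted over the list alone numbered 12, 11, 8, 6 and 9. The immune and interferon (0.218) and cholesterol (0.0577) lists did not pass with the authors' series table, nor the latter with a strict filter (0.212). Slide as a block left 4013 genes, and 3119 and 2539 within the scan days.

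**Figure D3:**
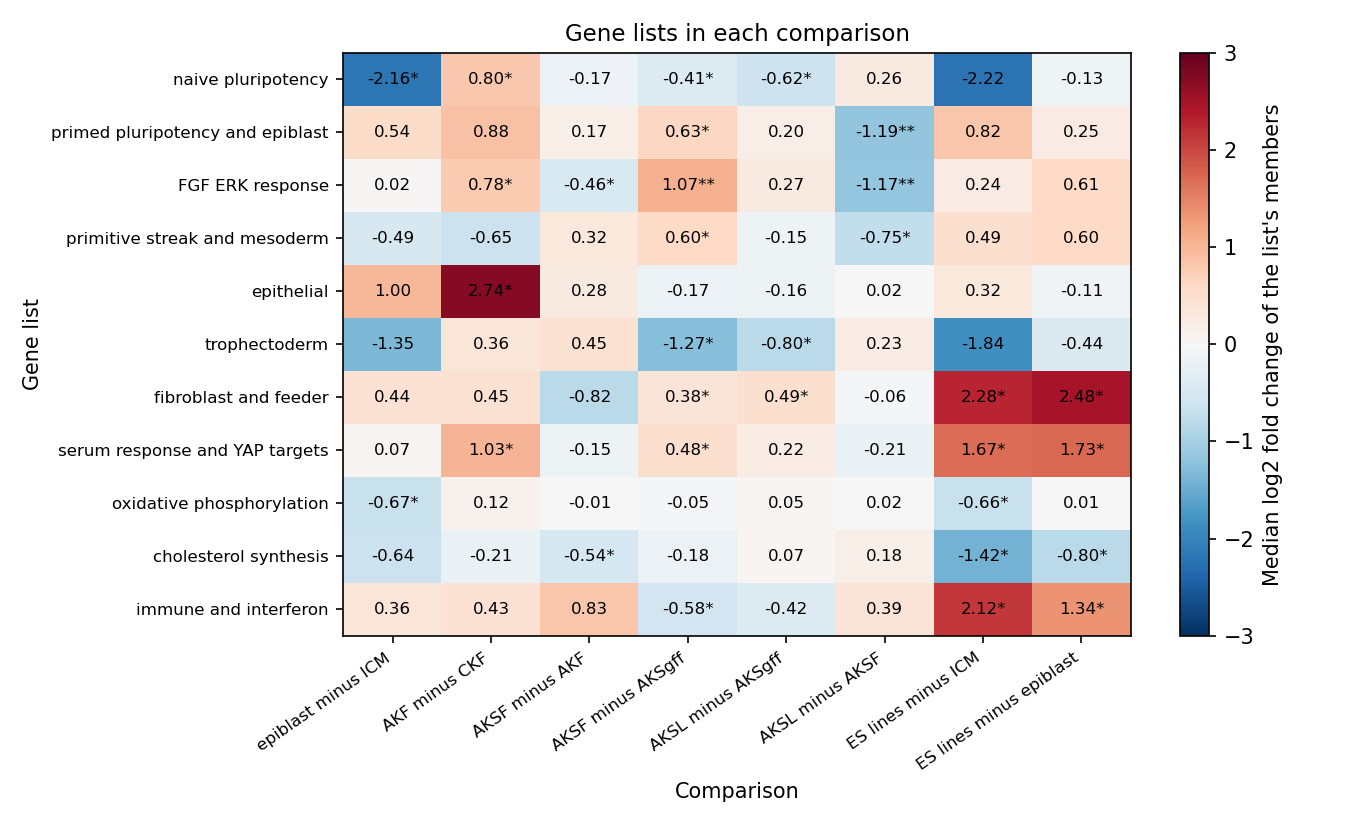
Median log2 fold change of the members of 11 gene lists (y axis) in each of the 8 comparisons (x axis), red for higher and blue for lower in the first-named group. A single asterisk marks a camera adjusted p under 0.05 and a double asterisk a call kept with an estimated correlation, as for the FGF and ERK list in AKSF against AKSgff (median 1.07) and in AKSL against AKSF (−1.17).

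The lines were also placed between ICM (0) and epiblast (1) over the 4081 genes that parted those tissues. Lines grown with FGF2 lay further along this axis. The mean position was 0.907 ± 0.0332 (SD, n = 2) for CKF, 0.874 ± 0.0169 (n = 2) for AKF, 0.862 ± 0.00796 (n = 2) for AKSF, 0.833 ± 0.00745 (n = 3) for AKSL and 0.763 ± 0.0179 (n = 2) for AKSgff. The 6 lines with FGF2 averaged 0.881 ± 0.0267 and the 5 without 0.805 ± 0.0398, a difference of 0.0758 in which every line with FGF2 stood above every line without (exact two-sided permutation p = 0.00216, the smallest that 462 splits can give, and adjusted p = 0.00216 over 2 relations). The permutations shuffled lines, whereas FGF2 was set by condition, so this p and those below do not allow for differences between conditions. This split is not of FGF2 alone, since 4 of the 6 lines with FGF2 (AKF and CKF) grew without fetal calf serum and all 5 lines without FGF2 grew with it, and CKF was also passaged in clumps. Among the conditions with serum, AKSF stood at 0.862, AKSL at 0.833 and AKSgff at 0.763, and these 3 were not tested on their own. The correlation across genes with the epiblast profile minus that with the ICM profile was 0.0534 ± 0.00325 with FGF2 and 0.0437 ± 0.00589 without, a difference of 0.00972 (exact two-sided permutation p = 0.00216, adjusted p = 0.00216). The correlation with the epiblast alone ran the other way: its mean r was 0.892 for CKF, 0.914 for AKF, 0.922 for AKSF, 0.926 for AKSL and 0.927 for AKSgff, so a higher position was not a closer likeness to the epiblast. With ICM, CKF had a mean r of 0.836 and AKSgff of 0.889. Between 50.7% (CKF) and 56.3% (AKSF) of the squared distance of the lines from the ICM lay along this axis, and the rest led away from it.

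Within the first scan day the difference in position was 0.0709 (exact permutation p = 0.0159) and within the second 0.0760 (exact permutation p = 0.00433), and with slide effects removed 0.0731 (exact permutation p = 0.00216). The first day had 4 lines with FGF2 and 5 without. The difference in correlation was 0.00855 (exact permutation p = 0.0317), 0.00988 (exact permutation p = 0.00216) and 0.00925 (exact permutation p = 0.00216). Among genes well above background on all 39 arrays the differences were 0.0452 (exact permutation p = 0.0628) and 0.00597 (exact permutation p = 0.0844), so neither call held there.

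**Figure D4:**
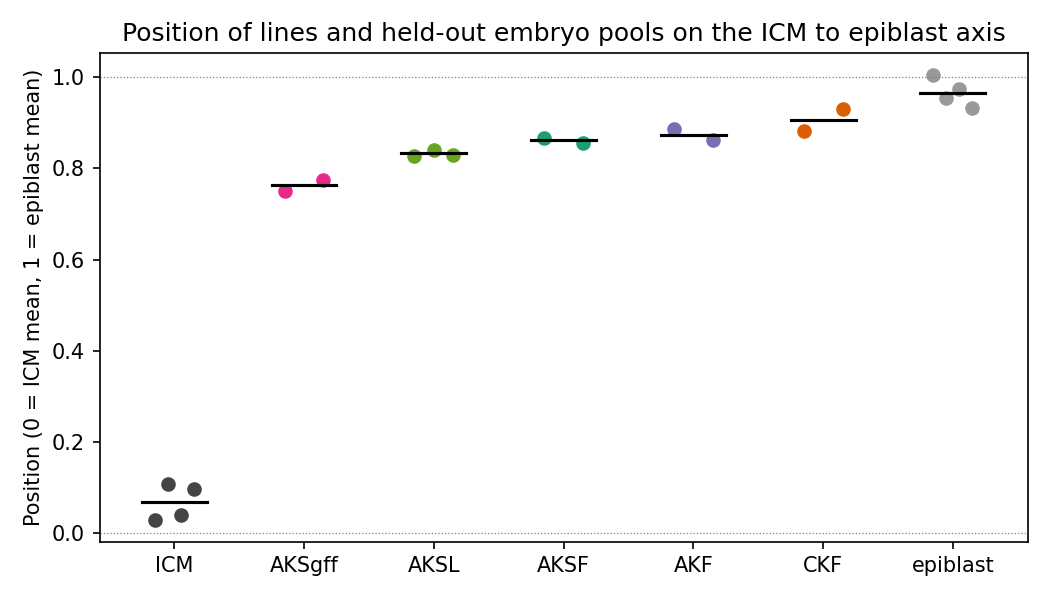
Position of each ES line and embryo pool (points) between the mean ICM profile at 0 and the mean epiblast profile at 1, by group. The 6 lines with FGF2 average 0.881 and the 5 without 0.805.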

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

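The tests of a minority of other cells and of weaker CKF arrays were chosen after the result was seen, and the other tests in this part before.

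A pair of arrays stood apart from the others of their group in the share of spots well above background, a measure of array quality. The first culture of AKF line 5 had 61.8%, against 66.5% to 69.3% in the other 5 AKF arrays. The third culture of AKSL line 20 had 57.0%, against 65.8% to 69.2% in the other 8 AKSL arrays. OTX2 was lowest in the first culture of AKSgff line 62, at −4.85, with −3.78 to −3.19 in the other 5 AKSgff arrays. COL1A1 was lowest in epiblast pool 4, at −5.95, with −4.75 to −4.68 in the other 3 pools. In all 63 sets of arrays were tested, and chance alone sets apart about 1 in 20, so the number set apart, 4, is about what chance gives. That number does not settle any single array. For the third culture of AKSL line 20 the gap to the next array was 0.723 of the group's range, with a threshold of 0.493. For COL1A1 in epiblast pool 4 it was 0.947, with a threshold of 0.829. A signal also lay in probes that the comparisons by gene leave out. Of the 15647 kept probes without exactly 1 gene name, 2569 differed between AKF and CKF.

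The counts between tissues were set against other splits of the same units. Every other split mixes the tissues, which widens the spread within groups and lowers the count, so these splits cannot exclude chance. Fitted as 2 groups alone, epiblast and ICM differed in 3401 genes, and none of the other 34 of the 35 splits of the 8 pools into 4 and 4 gave any (1 of 35 as many). For ES lines against ICM the count was 4720, and the highest of the other splits among 100 drawn gave 1317 (1 of 100 as many). For ES lines against epiblast it was 3901, and the highest other 206 (1 of 100 as many).

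Epithelial genes were lower in the CKF lines, passaged in clumps, than in the AKF lines. The tables argue against a minority of other cells in the CKF cultures, since the median fall of the 10 members was 2.74 on the log2 scale (SE 0.390, and 2.62 with dim genes at their bound), and the fall of CDH1 alone, at its bound, would need at least 91.2% of the cells to have been replaced. Slide is argued against by a median of 2.91 with slide as a block. Weaker CKF arrays are argued against because CKF arrays had 3.04 percentage points more spots well above background than AKF arrays. A loss of epithelial character in most cells of the CKF lines may explain it and stays open, and whether passaging or the particular lines led to it cannot be settled with separate lines in each condition.

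Fibroblast and contractile genes were higher in the ES lines than in ICM and epiblast (13 members, of which ACTA2, MMP2 and LOX are also on other lists). Scaling is argued against, since the smallest median rise over ICM under the other scalings was 1.48, with 2.28 as reported. RNA of fibroblasts cultured with the lines stays open as a candidate source: the 13 members moved together over the 11 lines with a median pairwise r of 0.380, against −0.00685 for the median and 0.197 for the 95th percentile of 1000 random lists matched on signal and spread (0.4% of them as high). The mean signal of COL1A2 was 3.53 in the lines and −1.83 in ICM, and that of COL3A1 2.03 and −6.41, while that of DCN was −4.85 and −3.65. The labels name no feeder cells, and expression of these genes by the ES cells themselves was not tested and stays open as well.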

How the results depend on the processing

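The tests of gene lists, position and correlation by slide and by scan day, and the counts without the 2 arrays of lowest detection and without the genes of chromosomes 16 and 20, were chosen after the data were seen. Over the genes named by the rule, without those not reported here, 19144 of 20244 values under other settings kept their direction and their side of the threshold, 583 lost the call, 510 gained it and 7 reversed. The reversed were, on the log2 scale, PAX6 in ES lines against ICM with normexp (0.73) and with the authors' series table (0.60), and with that table ACTA2 in epiblast against ICM (−0.0593) and, in ES lines against epiblast, RNF43 (0.17), APCDD1 (0.0664) and COX5B (0.23), with COX5B also at 0.00336 when centred on the array median; the cause was not tested. Among values of gene lists 2983 of 3196 stayed as they were, 117 lost the call, 96 gained it and none reversed. Quantile normalization, a floor for low signals, no filter on dim probes, the median over a gene's probes and limma's trend and robust settings left every count of genes within 1.5 times the reported one.

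With normexp 18 genes passed in AKSL against AKSgff. With the authors' series table AKSF against AKF gave 74, 336 in AKSF against AKSgff, 31 in AKSL against AKSgff and 155 in AKSL against AKSF. The cause was not tested. Among genes well above background on all arrays, which are fewer, the counts were 8, 73, 1 and 19, with 3493 in ES lines against ICM and 13 lists, and the differences between lines with and without FGF2 were 0.0452 in position and 0.00597 in correlation. Over all kept probes, which are more, 16643 passed in epiblast against ICM, 5520 in AKF against CKF, 77, 830, 72 and 315 in the 4 comparisons from AKSF against AKF to AKSL against AKSF, 22156 in ES lines against ICM and 17968 in ES lines against epiblast.

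With every culture as a replicate, which gives more values per group, the counts for AKF against CKF, AKSF against AKF, AKSF against AKSgff, AKSL against AKSgff and AKSL against AKSF were 2485, 512, 1046, 243 and 666 with no term for the line and 2177, 307, 774, 131 and 423 with the line as a random block, where AKSL against AKSF gave 220 higher and 203 lower (21 and 48 as reported). Shares higher also moved by more than 10 points in the other comparisons with few genes. AKSF against AKF gave 5 higher and 6 lower without AKSF line 19 and 4 and 0 without AKSF line 26 (9 and 19 as reported), and AKSL against AKSgff 97 and 208 on the first scan day and 2 and 1 on the second (1 and 4 as reported). They were 2258, 240, 822, 124 and 413 with slide as a block, and 2110, 245, 673, 95 and 350 with the culture letter or pool number as a block, a pairing by number only, where ES lines against epiblast gave 2450. In the same order from AKSF against AKF on they were 659, 1099, 305 and 777 within the first scan day and 146, 389, 3 and 229 within the second, where epiblast against ICM gave 1996 and ES lines against epiblast 2539, with fewer arrays in each day. The AKSF arrays of the first day were all of line 19. With only the groups compared in the fit, which leaves fewer units for the spread, limma gave 589 in AKF against CKF, 7 in AKSL against AKSF, and 0 in AKSF against AKF (1118 at an unadjusted p under 0.05) and in AKSL against AKSgff (694). Of the lists, 38 passed in all, 3 with an estimated correlation and 62 with fry.

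Leaving out each line or pool in turn gave 3726 to 4194 genes in epiblast against ICM, 438 to 757 in AKF against CKF, 0 (379 at an unadjusted p under 0.05 in limma) to 45 in AKSF against AKF, 50 to 90 in AKSF against AKSgff, 3 to 8 in AKSL against AKSgff, 15 to 66 in AKSL against AKSF, 4936 to 5218 in ES lines against ICM and 3724 to 4114 in ES lines against epiblast. A lone line left in a group is assumed to vary like the other groups. In the same runs 33 to 42 lists passed, and the difference between lines with and without FGF2 was 0.0597 to 0.0857 in position and 0.00756 to 0.0109 in correlation, past the test each time. The 2 arrays of lowest detection were the third cultures of AKSF line 26 (53.3% of spots well above background) and of AKSL line 20 (57.0%). Without these 2 arrays the counts were 4003, 1168, 30, 187, 4, 82, 5263 and 4177 in the order of the report, and without the genes of chromosomes 16 and 20 they were 3891, 1194, 27, 160, 4, 68, 5081 and 4059. Signal over background limits the folds of genes that lay well above background on no array of a side, which are given as bounds.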

Other observations

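All 4 measured germ cell genes were lower in the ES lines than in ICM: DPPA5, MAEL and PIWIL2, which act in germ cells, and the transcription factor TFAP2C, though the call of PIWIL2 ended on the first scan day (adjusted p = 0.0848). Among DNA methylation genes the methyltransferase DNMT3B, the glycosylase TDG and the dioxygenase TET2 were lower too. Neither list was tested as a set, since each had fewer than 5 members, and 5300 of 7678 genes differed in this comparison. Of 4 neuroectoderm genes MAP2, a neuronal microtubule protein, and NES were higher in the lines than in either tissue, PAX6 was higher than in the epiblast, and DLX5 was lower than in either tissue. The lists for definitive endoderm, primitive endoderm, Nodal and Activin signalling and stress passed in none of the 8 comparisons. For epiblast against ICM, 9 primitive endoderm genes rose and 3 fell (median 1.34, adjusted p = 0.205) and 5 stress genes fell (median −0.94, adjusted p = 0.0517).

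The test for a few co-regulated genes on a chromosome and the HOX list and its tests were chosen after the result was seen. The other tests of chromosomes were chosen before.

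In 3 lines most probes of a chromosome stood above the median of the other lines. In CKF line 4 the median shift of 188 probes on chromosome 20 was 0.53 on the log2 scale (1.45-fold), with 88.8% of the probes above the median of the other lines and 0.53 to 0.56 in single cultures. On chromosome 16 (426 probes) it was 0.28 in AKSL line 4 (79.1% of probes) and 0.28 in AKSgff line 3, and in the other 239 pairs of line and chromosome the same measure ran from −0.14 to 0.19. Slide and scan day are argued against for CKF line 4, whose 2 cultures, on 2 slides, both lay above that range. On chromosome 16 single cultures ran from 0.145 to 0.34 in AKSL line 4 and from 0.117 to 0.34 in AKSgff line 3. The lowest of these lie inside that range, so slide and scan day stay open there. The share of probes above that median, at least 78.9% in each of the 3 lines, decides nothing about co-regulated genes, since the lines were picked by their median shift. An extra copy of the chromosome in all or part of the cells may explain the shift and stays open, as a shift of at least 0.213 was present on either side of the middle of each chromosome, and no biological explanation in the design was tested.

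A candidate explanation for part of the difference between AKSF and AKSgff is that the growth factor raises HOX genes as a group, a hypothesis formed from the same data. Of 15 measured HOX genes 6 were higher in AKSF than in AKSgff and none lower (median 1.47, adjusted p = 4.46e-13, and 0.00578 with an estimated correlation), with medians of 1.54, 0.73 and 1.36 with slide as a block and within the scan days. The AKSF arrays of the first day were all of line 19. In AKSL against AKSF 6 were lower (median −1.49, adjusted p = 4.46e-13, and 0.00578 with an estimated correlation). That median is the value of HOXC6, which like HOXC4 and HOXD11 lay well above background on no array of either side, so no size is read from it. Both comparisons use the same 2 AKSF lines, and AKSF against AKF gave 1 gene higher. HOX genes were also higher in CKF than in AKF, both grown with FGF2, by 9 genes (median −3.82 for AKF minus CKF, adjusted p = 9.66e-11, and 0.00868 with an estimated correlation), so FGF2 is not the whole account and differences between lines stay open.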
